A study of Mus musculus with 24 samples.

How the data were processed

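Bulk RNA sequencing was done on prefrontal cortex of mice at postnatal day 40. The 24 libraries make 8 groups of 3, from 4 arms in each sex: wild type (WT) on vehicle, and mice heterozygous for a Dyrk1a allele named I48X in the labels (HT) on vehicle, fluoxetine or lithium. The kit named in the labels selects polyadenylated RNA and keeps the strand. Doses, the length of treatment and the counting setting for strand are not given in the sources used here. Nothing in the labels says that each library is a separate animal, so p-values measure only the spread between these samples, which may be partly technical.

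The authors deposited one table of normalized read signal for 18240 Ensembl genes in the 24 libraries. Per the submitters' processing notes, Salmon 0.11.2, R 3.6.0, DESeq2 1.19.11 and the mouse build GRCm38 were used, with no order or role stated. The deposited values look like read counts divided by a library's size factor: within a library they are whole multiples of a single read's value. With that value read from the lowest steps of each column, 100% of values came out whole in every library, within 0.01 of a read. A whole value can be a counted read or an estimate rounded before normalization, and the table does not tell these apart. In the column of HT vehicle female replicate 2 a read is worth 0.997, too close to 1 for an automatic check of the steps. That column rests on its low values only. The smallest mean over the 24 libraries in the table is 1.63, so genes below some level had already been left out. Gene symbols, biotypes and coordinates were taken from GENCODE M21 on GRCm38, which matched 18227 of the 18240 identifiers, all but 13.

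The recovered depth ran from 24133344 to 35940460 reads per library. No pair of libraries was as alike as sampling noise allows: the smallest chi-square per gene between any pair was 4.57, and 5.65 between libraries of one group, where noise alone gives 1.

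The main test was limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(value + 1), for the 16825 genes with a mean of at least 10, which left out 1415 genes. All 24 libraries shared one fit with 8 group means, and each contrast gave both sexes equal weight. Fold changes are on the log2(value + 1) scale, where the pseudocount of 1 understates the change of low genes. Adjusted p-values are Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. The median standard error of a log2 fold change was 0.10 for arms of 6, 0.15 for groups of 3, 0.21 for a difference between the sexes in an effect and 0.073 for males against females. Because the table holds normalized values, count tests were run only as alternatives, on the recovered reads: edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 (Wald).

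The steps were tested on data simulated from the real means, size factors and dispersions of 16825 genes, not their correlations. For 6 against 6 libraries, as in the genotype comparison, limma recovered 29.9% of 67 genes changed 1.25-fold, 65.7% of 67 changed 1.5-fold and 93.9% of 66 changed 2-fold, with 3 false calls, and made 0 calls where nothing was changed. On these data edgeR recovered 19, 41 and 61 with 2 false calls, and DESeq2 23, 50 and 63 with 18. A simulated list of 43 genes shifted by 0.15 was called and 0 of 30 unshifted were. Yet nearly all random splits of real libraries called lists and a few called genes (up to 3081), so these rates may not hold there.

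Gene lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The 31 lists hold 569 genes, of which 559 were tested. They cover cell types (excitatory and inhibitory neurons, astrocytes, myelin and mature oligodendrocytes, oligodendrocyte precursors and newly formed oligodendrocytes, microglia, endothelial cells and pericytes, choroid plexus and meningeal cells, striatal projection neurons, red blood cells), neuronal function (immediate early genes, neurotrophin and late activity genes, glutamate receptors and postsynaptic density, GABA-A receptors and inhibitory synapse, presynaptic vesicle release), metabolism (nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, cytosolic ribosomal proteins, cholesterol synthesis), signalling (Wnt and beta-catenin targets, inositol metabolism, serotonin receptors and turnover, glucocorticoid-induced genes, circadian clock and output, endoplasmic reticulum stress, heat shock, calcineurin and NFAT, extracellular matrix and perineuronal net, interferon response) and neurodevelopment (autism risk genes, chromatin regulators and the BAF complex). Each list was tested with camera at a preset correlation between genes of 0.01, adjusted over the 31 lists, and again with a correlation estimated from the data. The fry test asks whether a list's genes move, on balance, one way, and does not compare the list with other genes. A score per library, the mean log2 deviation of the list's members, was compared between arms with a two-sided exact permutation test within sex (400 arrangements), added after the data were seen.

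Genes are named by this rule. For the genotype, fluoxetine and lithium comparisons they are Dyrk1a, the called genes with a mean of at least 50 and the same direction in both sexes (up to 8 in each direction, and where fewer than 5 pass, the 5 genes with the smallest p given as values), and the members with the smallest p of up to 6 lists called by camera. Genes standing for the drugs' targets (Htr1a, Htr2a, Impa1, Axin2) may be given as values. The sex and other comparisons name the 5 called genes with the smallest p. Some genes that the rule names are not reported here.

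Per the labels, all 6 lithium libraries and 1 fluoxetine library (HT fluoxetine female replicate 3) are in batch P40_L2, and the other 17 are in P40_L1. Lithium and batch can be told apart only through that 1 library. The alternatives were a mean of at least 50, no filter beyond detection, a rescaling of libraries, a pseudocount of 8, a batch term, the replicate number as a block, fits of only the groups compared, an estimated correlation for lists, and leaving out each library in turn. Alternatives added after the data were seen were both count tests, an olfactory bulb score as a covariate, and leaving out the 6 libraries with the highest such score or the 4 with the highest Drd2 or Ttr. The olfactory bulb score is the mean log2 deviation of 9 genes (Cdhr1, Doc2g, Tbx21, Eomes, Th, Scgn, Sp8, Tshz1 and Trh) chosen after principal components had been seen and before any test of the list.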

Results

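The series compared prefrontal cortex transcripts of mice with a heterozygous Dyrk1a allele (HT) and wild-type (WT) mice at postnatal day 40. Some HT mice received fluoxetine, a serotonin reuptake inhibitor, or lithium, a mood stabiliser. There were 6 libraries in each of 4 arms (WT vehicle, HT vehicle, HT fluoxetine, HT lithium), 3 from females and 3 from males. A library is named by arm, sex and replicate number, as in HT vehicle female 1 or WT female 1. The 6 libraries with the highest score of olfactory bulb genes are called bulb-high, and 4 with the highest Drd2 or Ttr are called Drd2/Ttr-high. The recovered depth ran from 24133344 to 35940460 reads. Levels are normalised read counts as mean ± SD over the 6 libraries of an arm, and fold changes are log2 values ± standard error from limma.

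Dyrk1a, the kinase gene that carries the allele (ENSMUSG00000022897, chromosome 16, 94570010 to 94695517 on GRCm38), was not lower in the libraries labelled HT. It stood at 2200 ± 90.8 (SD, n = 6) in WT vehicle and at 2355 ± 61.2 in HT vehicle, 7.1% higher, with 6 of 6 HT vehicle libraries above the WT mean (two-sided exact permutation test over 924 arrangements, p = 0.0108). HT fluoxetine libraries held 2476 ± 97.5 and HT lithium libraries 2447 ± 113, 12.5% and 11.2% above WT (exact permutation p = 0.00217 and 0.00649). Across all genes the HT against WT difference on vehicle, 0.10 ± 0.04, did not pass (limma adjusted p = 1); for HT fluoxetine against WT, 0.17, DESeq2 called Dyrk1a (adjusted p = 0.0103) and limma and edgeR did not. A premature stop need not lower the RNA of its gene, so this level does not check the genotype labels.

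**Figure D1:**
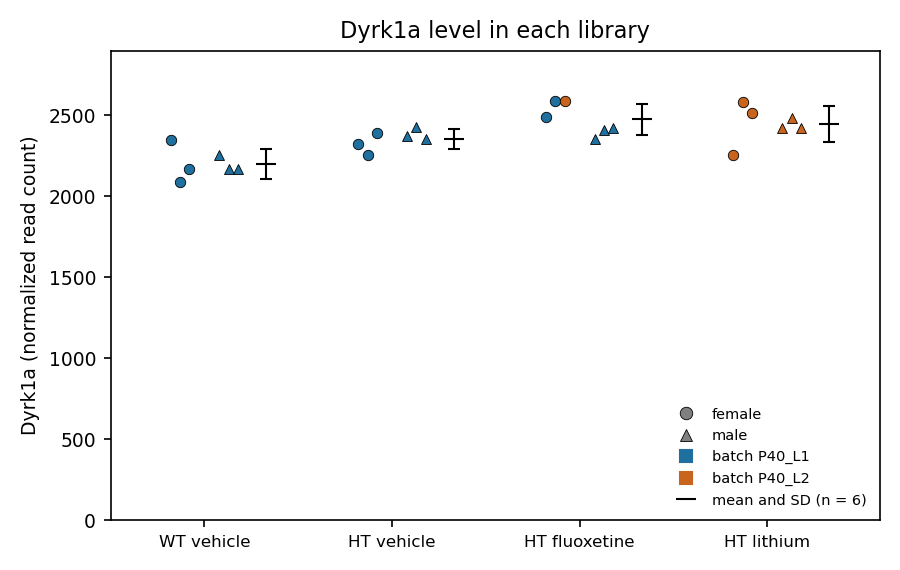
Normalised Dyrk1a read count in each library by arm, with circles for females, triangles for males, blue for batch P40_L1 and orange for batch P40_L2; horizontal and vertical black lines give the mean and SD of 6 libraries. WT vehicle libraries lie between 2088 and 2349 and HT vehicle libraries between 2254 and 2431.

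In HT against WT mice on vehicle, the 14 microglial marker genes were all higher, with a median log2 fold change of 0.11 (0.20 in females, 0.002 in males), and 6 of 6 HT libraries scored above the WT mean. They include the lysosomal protease Ctss (0.15 ± 0.05, from 1343 ± 145 to 1487 ± 53.0), the complement gene C1qc (0.22 ± 0.08, from 994 ± 83.6 to 1155 ± 101), the growth factor receptor Csf1r (0.12 ± 0.06) and Tmem119 (0.14 ± 0.07). All 15 neurotrophin and late activity genes were lower, by a median of -0.14, with 6 of 6 HT libraries below the WT mean. Among them were the postsynaptic scaffold Homer1 (-0.37 ± 0.14, from 4455 ± 296 to 3464 ± 550), the prohormone convertase Pcsk1 (-0.26 ± 0.09, from 1490 ± 135 to 1247 ± 138), the sorting receptor Sorcs3 (-0.14 ± 0.06) and the synaptic pentraxin Nptx2 (-0.14 ± 0.07). Cytosolic ribosomal protein genes were higher in 41 of 46 cases by a median of 0.059. Rpl10a stood at 0.15 ± 0.07, Rps14 at 0.13 ± 0.06 and Rpl19 at 0.07 ± 0.04, while Rps27 was lower at -0.62 ± 0.29. Camera called these 3 lists (adjusted p = 1.15e-06, 1.35e-06 and 2.99e-05), and none held at adjusted p = 0.3, 0.3 and 0.666 with an estimated correlation. Leaving out any of the 12 libraries kept each camera call. The ribosomal median was 0.030 without HT vehicle male 1, 0.029 without WT female 3 and 0.097 without HT vehicle male 2, and it was -0.013 in females and 0.11 in males. The exact permutation test of scores gave p = 0.095 for microglia, 0.02 for late activity genes and 0.275 for ribosomal proteins (adjusted p = 0.651, 0.62 and 0.853).

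Autism risk genes were lower in 31 of 40 cases in HT mice, by a median of -0.037. The ubiquitin ligase gene Cul3 stood at -0.13 ± 0.06, the adhesion gene Dscam at -0.07 ± 0.04, Asxl3 at -0.14 ± 0.09 and Katnal2 on the other side at 0.20 ± 0.11 (camera adjusted p = 0.0109, and 0.3 with an estimated correlation). Leaving out HT vehicle male 3 ended that call, with a median of -0.022. Astrocyte markers were higher in 12 of 14 cases by a median of 0.045 (adjusted p = 0.0259, and 0.369 with an estimated correlation). Among them were the folate enzyme Aldh1l1 (0.14 ± 0.05), the receptor Fgfr3 (0.12 ± 0.06), the gap junction gene Gjb6 (0.18 ± 0.09) and the transcription factor Sox9 (0.11 ± 0.07). That call ended without HT vehicle females 2 or 3, HT vehicle male 3 or WT male 1, with medians of 0.026 to 0.067. It was kept at 0.081, 0.080 and 0.068 without HT vehicle male 2, WT female 2 or WT male 3. Choroid plexus and meningeal genes were higher in 10 of 12 cases by a median of 0.16 (adjusted p = 0.0259, and 0.666 with an estimated correlation). Clic6 stood at 1.37 ± 0.67, Kcnj13 at 0.49 ± 0.28, the thyroid hormone carrier Ttr at 1.93 ± 1.27 and Kl at 0.38 ± 0.33. Ttr stood at 3407 in HT vehicle female 1 and at 4.42 to 62.8 in the other 5 HT vehicle libraries. The choroid plexus call ended without HT vehicle female 2, HT vehicle male 3, WT female 3 or WT males 1 or 2, with medians of 0.019 to 0.15, and with a mean of at least 50 normalised counts (0.11). It was kept at 0.24 without HT vehicle male 2 and 0.35 without WT male 3. Without the 6 bulb-high libraries all 3 calls ended, with medians of -0.019 for autism risk genes, 0.033 for astrocytes and, turned in sign, -0.060 for choroid plexus genes. With the bulb score as a covariate the last 2 lists stood at 0.085 and 0.29, and without the 4 Drd2/Ttr-high libraries astrocytes stood at 0.078.

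Glutamate receptor and postsynaptic density genes (18 of 24 lower, median -0.037), cholesterol synthesis genes (16 of 20 lower, median -0.058) and heat shock genes (11 of 15 lower, median -0.064) were also called lower by camera in HT mice. Their adjusted p-values were 0.0303, 0.0259 and 0.0259, against 0.572, 0.848 and 0.572 with an estimated correlation. All 3 calls ended without HT vehicle female 2, HT vehicle male 3 or WT male 1. The glutamate call also ended without HT vehicle male 1, WT female 3 or WT male 2. The cholesterol call also ended without WT female 1 or WT male 2, and the heat shock call without WT female 1. Without these libraries the medians were -0.041 to -0.015 for glutamate genes, -0.053 to -0.005 for cholesterol genes and -0.057 to -0.031 for heat shock genes. Calls were kept without HT vehicle female 3 (glutamate -0.070, cholesterol -0.10), WT female 2 (-0.069, -0.11), HT vehicle male 2 (glutamate -0.064) and HT vehicle male 1 (cholesterol -0.089). All 3 calls also ended without the 6 bulb-high libraries (medians -0.002, -0.025 and -0.041) and without the 4 Drd2/Ttr-high libraries (-0.044, -0.041 and -0.066). With the bulb score as a covariate the glutamate and cholesterol medians were -0.080 and -0.10. Scores of the glutamate and cholesterol lists were lower at higher olfactory bulb scores, which differed by -0.90 between HT and WT vehicle libraries (exact permutation p = 0.465).

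No single gene passed the main test of genotype. limma called 0 of 16825 genes, with 455 at an unadjusted p under 0.05 where 841 would arise by chance, and edgeR and DESeq2 called 0 each. Without WT male 2, limma called 1. The smallest p-values, given here as values that did not pass, belonged to the ubiquitin ligase gene March11 (ENSMUSG00000022269, chromosome 15, 26309048 to 26409576), lower by -0.43 ± 0.08 in HT (107.5 ± 12.6 against 79.3 ± 8.24, 6 of 6 below the WT mean, adjusted p = 0.776). The next were Eva1a (0.37 ± 0.08), Fam221b (0.44 ± 0.10), the hypoxia-inducible factor gene Hif3a (0.56 ± 0.13) and the Max-binding repressor Mxd4 (0.23 ± 0.05), each with an adjusted p of 1. The number of lists called by camera was 9 and moved with single libraries, to 14 without HT vehicle female 1, 16 without HT vehicle male 2 and 4 without WT male 1.

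**Figure D2:**
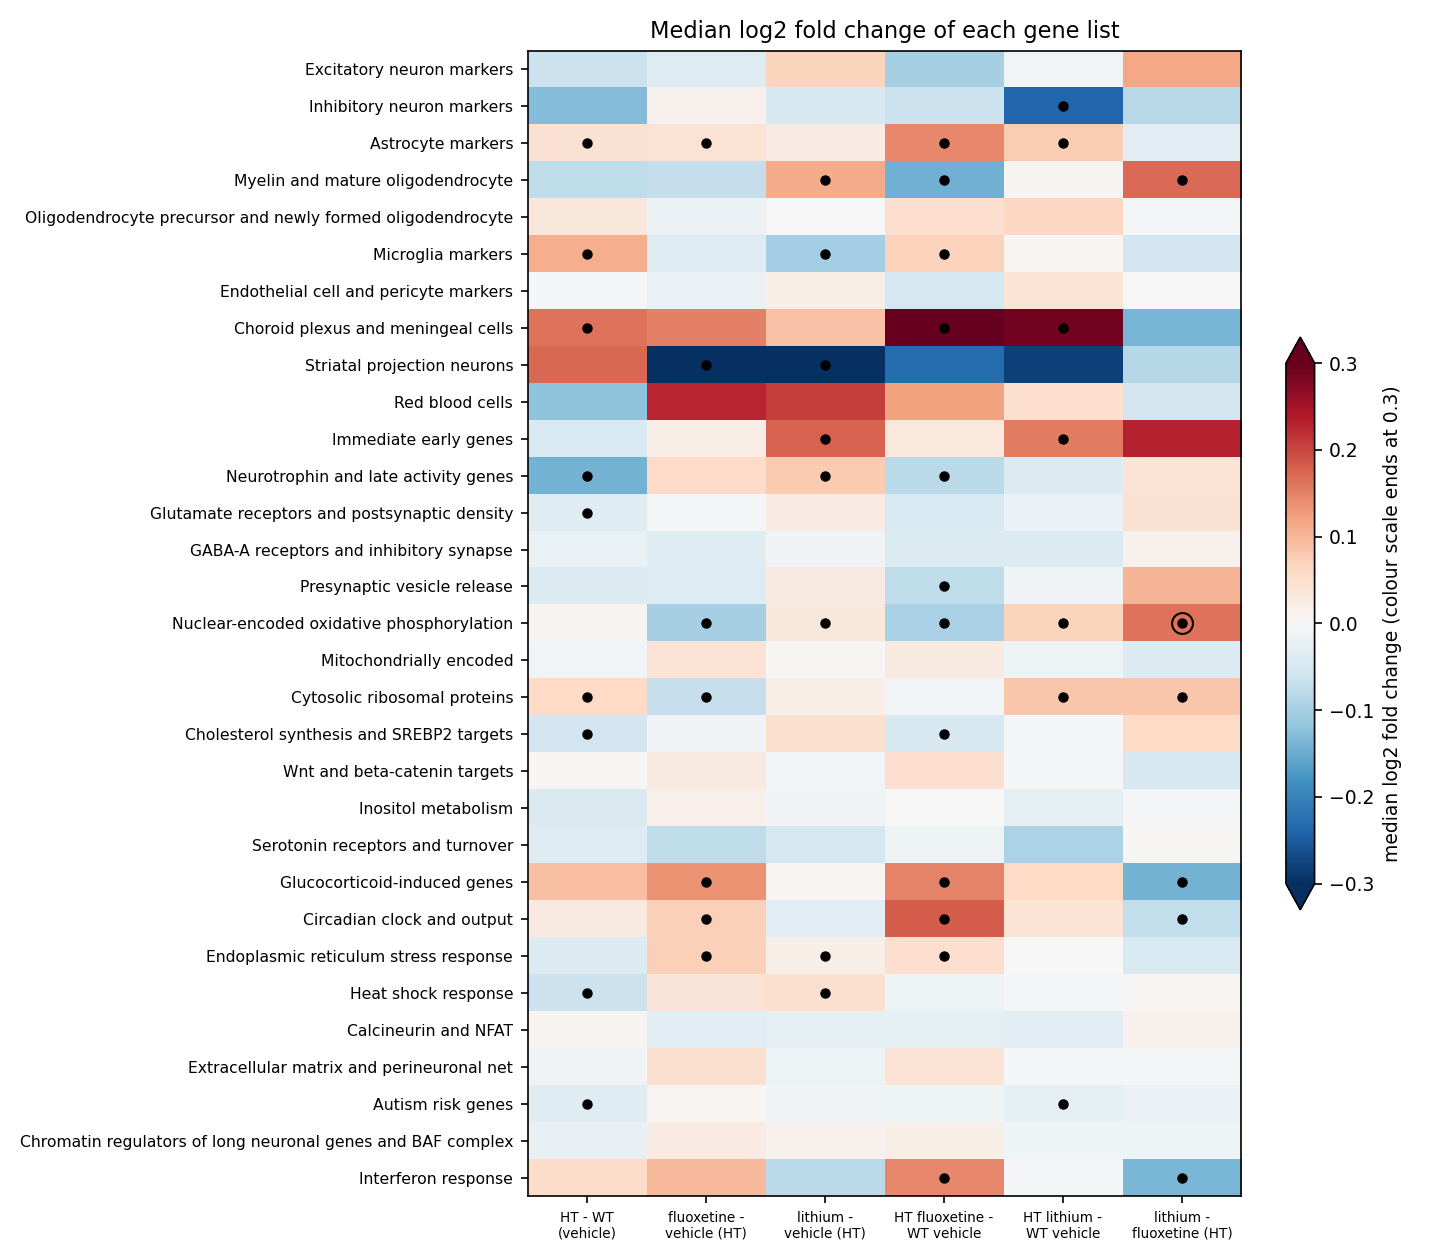
Median log2 fold change of each of 31 gene lists (lines) in 6 comparisons between arms of 6 libraries (columns), red for higher and blue for lower; a filled dot marks a camera adjusted p under 0.05 at a preset correlation of 0.01 and a ring marks one under 0.05 with an estimated correlation. The single ring is oxidative phosphorylation in lithium against fluoxetine, with a median of 0.16.

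With fluoxetine in HT mice, 42 of 43 nuclear-encoded oxidative phosphorylation genes were lower than in HT vehicle, by a median of -0.099, and 6 of 6 fluoxetine libraries scored below the vehicle mean. Examples are the complex IV associated gene Ndufa4 (-0.20 ± 0.04, from 4185 ± 246 to 3650 ± 207), the cytochrome oxidase subunit Cox7b (-0.26 ± 0.06), the ATP synthase subunit Atp5e (-0.25 ± 0.06) and the complex III subunit Uqcrq (-0.29 ± 0.07). Ndufs3, a complex I subunit outside that list (ENSMUSG00000005510, chromosome 2, 90894634 to 90904827), fell by 0.23 ± 0.04, from 2326 ± 74.8 to 1981 ± 73.3, with 6 of 6 libraries below the vehicle mean (limma adjusted p = 0.0251). P4ha1, a collagen prolyl hydroxylase gene (ENSMUSG00000019916, chromosome 10, 59323296 to 59373304), rose by 0.31 ± 0.05, from 928 ± 49.0 to 1153 ± 30.95, with 6 of 6 libraries above (adjusted p = 0.0233). These 2 genes were the only ones limma called, of 961 at an unadjusted p under 0.05 where chance gives 841, and edgeR called the same 2 (adjusted p = 0.0208 for each), which were also among 16 called by DESeq2.

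Camera called the oxidative phosphorylation list (adjusted p = 2.09e-16), and limma called 10 members lower adjusted over the list alone, against 0 over all genes, where DESeq2 called Ndufa4 and Cox7b. The call did not hold at adjusted p = 0.146 with an estimated correlation. The fry test gave an adjusted p of 0.0429 and the exact permutation test of scores p = 0.005 (adjusted p = 0.155). Leaving out any of the 12 libraries kept the camera call, and without the 6 bulb-high libraries the median was -0.17. Within batch P40_L1, that is without fluoxetine female 3, the median was -0.12, Ndufs3 stood at -0.25 (adjusted p = 0.0359) and P4ha1 at 0.31 (0.0660), so 1 gene was called. The P4ha1 call ended without any single fluoxetine library and without HT vehicle females 1 or 2 or male 1. The Ndufs3 call ended without any fluoxetine library other than female 3 and without any HT vehicle library other than male 3. Over all 12 omissions the values ranged from 0.29 to 0.34 for P4ha1 (adjusted p = 0.0171 to 0.116) and from -0.25 to -0.21 for Ndufs3 (0.0359 to 0.137). Both calls also ended in fits of only the groups compared, without those 6 libraries and without the 4 Drd2/Ttr-high libraries, and the P4ha1 call with a batch term (0.28 to 0.31 for P4ha1, -0.25 to -0.20 for Ndufs3).

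Several stress and hormone lists were higher with fluoxetine. All 15 glucocorticoid-induced genes were higher, by a median of 0.14, with -0.007 in females and 0.29 in males. The ERBB inhibitor Errfi1 stood at 0.13 ± 0.05, the glucocorticoid-induced leucine zipper gene Tsc22d3 at 0.21 ± 0.12, the lipid droplet gene Plin4 at 0.55 ± 0.30 and the sulfotransferase Sult1a1 at 0.18 ± 0.10. Clock genes were higher in 11 of 16 cases by a median of 0.071, with 3 higher in limma adjusted over the list alone and 0 over all genes, where DESeq2 called Per2. The period genes Per2 (0.43 ± 0.08, from 1477 ± 81.8 to 1991 ± 157, adjusted p over all genes 0.217) and Per1 (0.28 ± 0.08) and the repressor Bhlhe40 (0.37 ± 0.11) had the smallest p, and Cry1 stood at 0.26 ± 0.11. Endoplasmic reticulum stress genes were higher in 17 of 21 cases by a median of 0.072, with 3 higher in limma adjusted over the list alone and 0 over all genes. Of these, the transcription factor Xbp1 stood at 0.15 ± 0.04, the chaperone Hspa5 at 0.16 ± 0.04, and the disulfide isomerases Pdia4 and Pdia6 at 0.22 ± 0.06 and 0.09 ± 0.04. The camera adjusted p-values were 2.0e-04, 3.4e-04 and 7.91e-05, and all 3 calls were kept without any single library, with a clock median of 0.043 without fluoxetine male 2. With an estimated correlation the adjusted p was 0.239, 0.308 and 0.238. Cytosolic ribosomal protein genes were lower in 39 of 46 cases by a median of -0.070 (camera adjusted p = 3.61e-06, and 0.896 with an estimated correlation). Rpl38 stood at -0.28 ± 0.08, Rps20 at -0.18 ± 0.06, Rpl10a at -0.20 ± 0.07 and Rps29 at -0.36 ± 0.13. The ribosomal median was -0.12, -0.036 and -0.11 without fluoxetine female 1, female 2 or male 1 and -0.037 without HT vehicle male 1. Without the 4 Drd2/Ttr-high libraries the ribosomal call ended, with a median of -0.008, and clock genes stood at 0.046. Without the 6 bulb-high libraries the medians were -0.14 and 0.11.

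Astrocyte markers were higher with fluoxetine in 11 of 14 cases by a median of 0.043, 0.012 in females and 0.11 in males (camera adjusted p = 0.0466, and 0.508 with an estimated correlation). The call ended without fluoxetine female 1, fluoxetine males 1 or 2, HT vehicle females 1 or 2 or HT vehicle males 1 or 2, with medians of 0.029 to 0.065, and with a mean of at least 50, in the fit of only the groups compared, with the bulb score as a covariate and without the 4 Drd2/Ttr-high libraries (0.043 to 0.053). Genes of striatal projection neurons were lower in 13 of 13 cases by a median of -0.41 (adjusted p = 0.0410, and 0.896 with an estimated correlation). Among them were the phosphodiesterase Pde10a (-0.67 ± 0.33), the sodium channel subunit Scn4b (-0.78 ± 0.51) and the dopamine receptor Drd2 (-0.84 ± 0.87). Drd2 stood at 1379 in HT vehicle male 1 and at 16.1 to 112 in the other 5 HT vehicle libraries, and without that library the list's median was 0.12. The striatal call also ended without fluoxetine females 1 or 3, fluoxetine males 1 or 3, or HT vehicle females 1 or 3, with a batch term (-0.37), in the fit of only the groups compared, with the bulb score as a covariate (-0.31) and without the 4 Drd2/Ttr-high libraries (-0.075, where the test turned to higher). It was kept at -0.69 without fluoxetine male 2 and -0.68 without HT vehicle male 3. The number of lists called by camera was 7, and 12 without fluoxetine female 2. Klf11, a Krüppel-like repressor (-0.32 ± 0.06, adjusted p = 0.217), and Zfp667 (0.28 ± 0.06, adjusted p = 0.255) had the next smallest p and did not pass in limma, while DESeq2 called both. Dyrk1a differed by 0.07 ± 0.04, and the serotonin receptor genes Htr1a and Htr2a by -0.22 ± 0.27 and -0.12 ± 0.15. The olfactory bulb score was 0.84 higher in fluoxetine than in vehicle libraries (exact permutation p = 0.55).

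**Figure D3:**
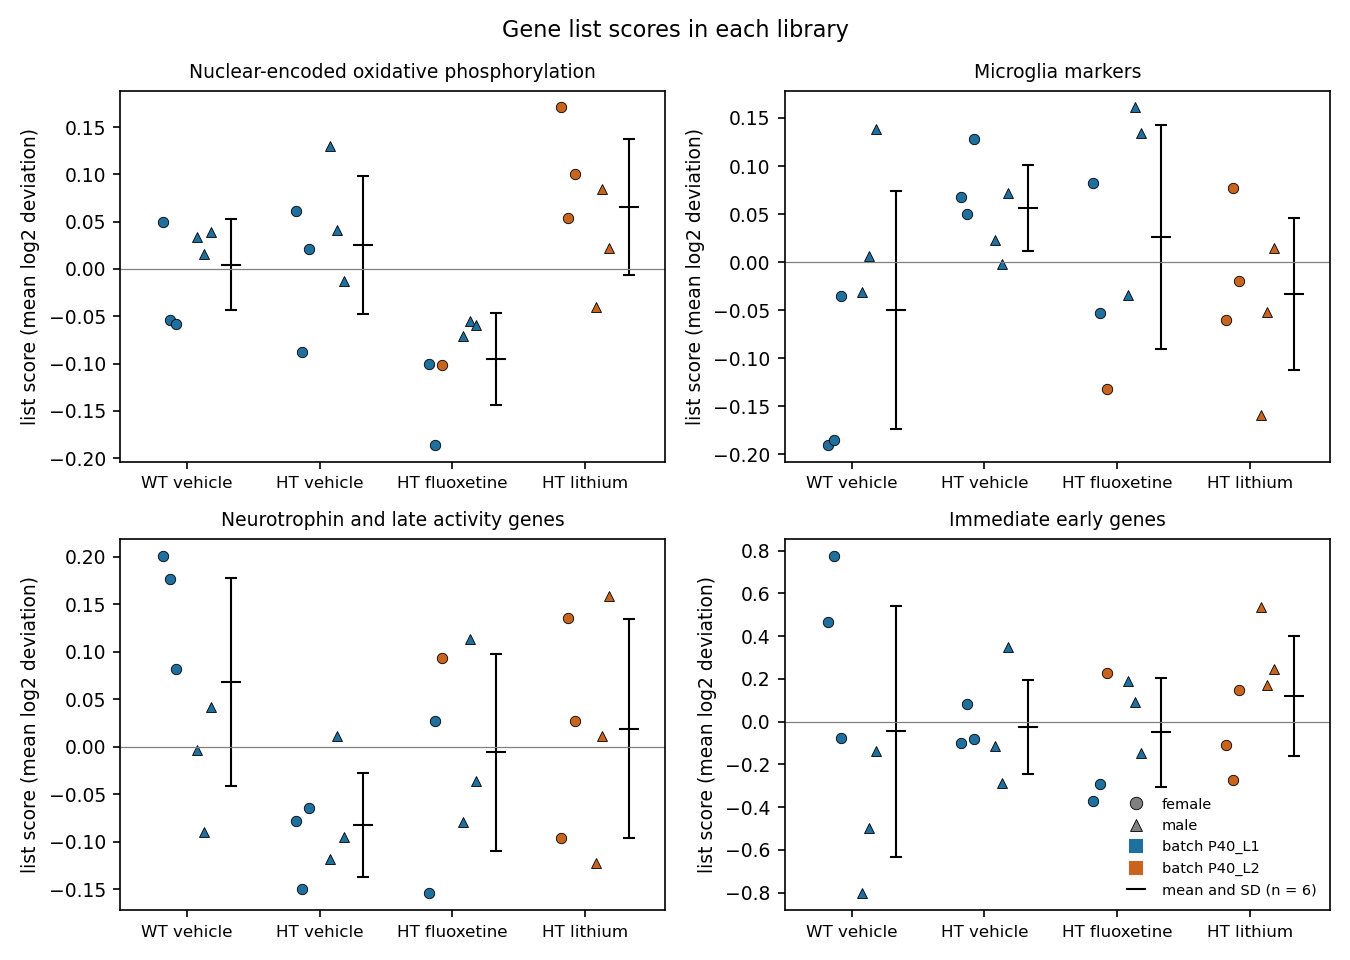
Scores (mean log2 deviation of a list's genes from their mean over libraries) of 4 gene lists in each library by arm, with circles for females, triangles for males, blue for batch P40_L1 and orange for batch P40_L2; black lines give the mean and SD of 6 libraries. For oxidative phosphorylation the fluoxetine library furthest from the others lies at -0.19, and all 6 fluoxetine libraries lie below the vehicle mean.

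Against vehicle in HT mice, lithium libraries lacked reads of Gm28048, a protein-coding gene model (ENSMUSG00000098650, chromosome 11, 22834744 to 22982090). They also lacked reads of the ribosomal pseudogene Rpl15-ps3 (ENSMUSG00000061167, chromosome 9, 22185607 to 22186221). Both are listed at 0 in all 6 lithium libraries, against 117 ± 32.1 and 54.5 ± 37.3 in HT vehicle. The fitted fold changes are no bound because they depend on the pseudocount (limma adjusted p = 0.0463 and 0.0486). Both were also at 0 in the fluoxetine library of the lithium batch, whereas in the 17 libraries of the other batch Gm28048 had 0 to 161 reads and Rpl15-ps3 had 6 to 182. Rpl15-ps3 can share reads with Rpl15 and its other copies, so its level is uncertain. These were the 2 genes limma called, of 463 at an unadjusted p under 0.05 where chance gives 841; edgeR called 0 and DESeq2 called 3, adding the pseudogene Gm12671. Each of the 12 omissions of a library ended both calls (adjusted p = 0.105 to 0.182 for Gm28048 and 0.0841 to 0.246 for Rpl15-ps3). Both also ended with a pseudocount of 8, with a batch term, without the 6 bulb-high libraries and without the 4 Drd2/Ttr-high libraries.

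Among gene groups, all 14 microglial markers were lower with lithium than with vehicle in HT mice, by a median of -0.10, with 5 of 6 lithium libraries below the vehicle mean. They include Ctss (-0.12 ± 0.05), the fractalkine receptor Cx3cr1 (-0.12 ± 0.07) and the integrin Itgam (-0.14 ± 0.09). The camera call (adjusted p = 1.07e-04) was kept without any single library and did not hold at adjusted p = 0.825 with an estimated correlation. The exact permutation test of scores gave p = 0.04 (adjusted p = 0.62). With a batch term the median turned to 0.11. The olfactory bulb score differed by 0.11 between lithium and vehicle libraries (exact permutation p = 0.93).

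Immediate early genes were higher with lithium in 17 of 20 cases by a median of 0.18, with -0.072 in females and 0.36 in males. The nuclear receptor Nr4a3 stood at 0.53 ± 0.16, the zinc finger factors Egr4 and Egr1 at 0.37 ± 0.17 and 0.25 ± 0.13 and the phosphatase Dusp6 at 0.29 ± 0.14. Late activity genes were higher in 14 of 15 cases by a median of 0.078. Nptx2 stood at 0.17 ± 0.07, Gpr3 at 0.28 ± 0.14, the neurotrophin Bdnf at 0.26 ± 0.16 and the cyclooxygenase Ptgs2 at 0.19 ± 0.13. Camera gave an adjusted p of 0.00185 for each, against 0.912 and 0.825 with an estimated correlation. With a batch term immediate early genes turned to -0.32 and were called lower, and late activity genes turned to -0.069, not called. The first call ended without lithium female 3, lithium male 1 or HT vehicle male 2 (medians 0.036 to 0.12). The second ended without lithium male 3 or HT vehicle female 2 (0.060 to 0.075). Without the 4 Drd2/Ttr-high libraries the immediate early call ended (0.15), and without the 6 bulb-high libraries or HT vehicle male 3 its median was 0.30. Late activity genes stood at 0.14, 0.041 and 0.12 without lithium female 1, female 2 or male 1 and 0.13 without HT vehicle male 2.

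Oxidative phosphorylation genes were higher with lithium in 39 of 43 cases by a median of 0.035, with 0.11 in females and -0.036 in males. Cox7c stood at 0.14 ± 0.05, Ndufb5 at 0.10 ± 0.04, Atp5g1 at 0.11 ± 0.07 and Ndufa4 at 0.07 ± 0.04 (camera adjusted p = 1.07e-04, and 0.825 with an estimated correlation). That call ended without HT vehicle female 2, with a median of 0.005, and with a batch term the median was 0.009 and the test turned to lower. It also ended without the 6 bulb-high libraries (0.020), and without the 4 Drd2/Ttr-high libraries the median was 0.069. It was 0.018 to 0.021 without lithium female 1, lithium male 2 or HT vehicle male 3, and 0.053 to 0.060 without lithium male 1, HT vehicle females 1 or 3 or HT vehicle male 1. Heat shock genes were higher in 13 of 15 cases by a median of 0.048. The inducible chaperones Hspa1b and Hspa1a stood at 0.38 ± 0.15 and 0.21 ± 0.10, a near-identical pair that can share reads, Chordc1 at 0.08 ± 0.06 and Hspb1 at 0.14 ± 0.13 (adjusted p = 0.00753, and 0.825 with an estimated correlation). Leaving out HT vehicle female 2 or male 3 ended the heat shock call (medians 0.026 to 0.032; 0.030, kept, without lithium male 3), as did a batch term (0.022) and leaving out the 6 bulb-high libraries (0.019), while without the 4 highest in Drd2 or Ttr the median was 0.079. Striatal projection neuron genes were lower in 12 of 13 cases by a median of -0.42, -0.092 in females and -0.88 in males (adjusted p = 0.00185, and 0.912 with an estimated correlation). Drd2 stood at -1.36 ± 0.87, Pde10a at -0.49 ± 0.33, Gpr6 at -0.82 ± 0.57 and Syndig1l at -0.95 ± 0.75. The median was -0.070 without HT vehicle male 1, the library with the high Drd2, which ended the call. A batch term (-0.16) and leaving out the 4 (0.001) ended it too, and without the 6 the median was -0.85; without HT vehicle male 3 it was -0.81.

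Endoplasmic reticulum stress genes (15 of 21 higher, median 0.018) and myelin genes (16 of 17 higher, median 0.11) were just past the threshold with lithium (camera adjusted p = 0.0497 for each, and 0.912 and 0.965 with an estimated correlation). The first call ended without lithium females 2 or 3, lithium males 1 or 3, HT vehicle female 2 or HT vehicle males 1 or 3 (medians 0.006 to 0.027). The second ended without lithium females 1 or 3, lithium males 1 or 2, HT vehicle female 2 or HT vehicle males 2 or 3 (medians -0.006 to 0.12). The first also ended with rescaling by trimmed means, a batch term, the fit of only the groups compared, the bulb score as a covariate and without either set of libraries (0.005 to 0.038). The myelin call ended with rescaling, a mean of at least 50 and the covariate (0.11 each) and without the 6 bulb-high libraries (0.009), where the test turned to lower; it was kept at 0.48 with a batch term, 0.31 without the 4, 0.24 without lithium female 2 and 0.27 without HT vehicle male 1. The endoplasmic reticulum call was kept at 0.038 without HT vehicle female 1, and its medians were 0.070 in females and -0.019 in males. Camera called 8 lists with lithium, 5 without lithium female 3 and 3 without HT vehicle female 2. Lrrc75a (0.20 ± 0.04, adjusted p = 0.328), Gm12671 (139 ± 80.9 in vehicle and listed at 0 with lithium, adjusted p = 0.346) and the membrane skeleton gene Epb41 (-0.34 ± 0.08, adjusted p = 0.703) had the next smallest p and did not pass in limma. Dyrk1a differed by 0.05 ± 0.04, and the lithium-sensitive phosphatase gene Impa1 and the Wnt target Axin2 by -0.03 ± 0.04 and -0.01 ± 0.06.

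The difference between the drugs was clearest in the respiratory chain, where all 43 nuclear-encoded oxidative phosphorylation genes were higher with lithium than with fluoxetine, by a median of 0.16. This list rose at both correlation settings: the camera adjusted p was 1.43e-29, and it was 0.0134 with an estimated correlation, while fry gave 0.00184 and the exact permutation test of scores p = 0.005, the smallest it can give (adjusted p = 0.0775). Of its members, limma called 19 adjusted over the list alone and 1 over all genes, where DESeq2 called 8, and 6 of 6 lithium libraries scored above the fluoxetine mean. limma called 4 genes, all higher with lithium. Ndufa4 is one (ENSMUSG00000029632, chromosome 6, 11900292 to 11907497; 3650 ± 207 with fluoxetine and 4376 ± 210 with lithium, 0.26 ± 0.04, adjusted p = 0.0395). The others were the complex I subunits Ndufb6 (0.30 ± 0.05) and Ndufs3 (0.22 ± 0.04, adjusted p = 0.0395 for each), outside the list, and the COP9 signalosome gene Cops9 (0.35 ± 0.06, adjusted p = 0.0470). Each was higher in 6 of 6 lithium libraries than the fluoxetine mean. edgeR called the same 4, as did DESeq2 among 30, and 941 genes had an unadjusted p under 0.05. Random lists matched on expression and exon length were not drawn here, so a shift common to such genes (-0.055 with fluoxetine) stays open. The list's call was kept without any single library (medians 0.13 to 0.19), but all lithium libraries and 1 fluoxetine library are in batch P40_L2. Without that fluoxetine library, female 3, limma called 6 genes, among them Ndufa4 and Ndufs3 (adjusted p = 0.00934 and 0.0197) but not Ndufb6 or Cops9. The 4 gene calls ended in 9 (Ndufa4), 11 (Ndufb6), 10 (Ndufs3) and 11 (Cops9) of 12 omissions. All 4 ended without fluoxetine females 1 or 2 or males 1 or 3, any lithium female, or lithium males 2 or 3. All but Ndufa4 also ended without fluoxetine male 2 (adjusted p = 0.00934 to 0.152 over omissions). All 4 also ended with a batch term (Ndufa4 0.14, Ndufb6 0.36, Ndufs3 0.12 and Cops9 0.29, where 1 gene was called), in the fit of only the groups compared (0 genes called) and without the 4 Drd2/Ttr-high libraries. All but Ndufb6 ended without the 6 bulb-high libraries, and Cops9 also with rescaling by trimmed means and with no filter on low values.

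Ribosomal protein genes were higher with lithium than with fluoxetine in 42 of 46 cases by a median of 0.083, with 2 higher in limma adjusted over the list alone and 0 over all genes (camera adjusted p = 4.99e-09, and 0.894 with an estimated correlation). Glucocorticoid-induced genes were lower in 15 of 15 cases by a median of -0.14 (adjusted p = 5.28e-04, and 0.376 with an estimated correlation; exact permutation p = 0.005, adjusted p = 0.0775), and clock genes in 14 of 16 by a median of -0.075 (adjusted p = 3.98e-04, and 0.376 with an estimated correlation). The clock call ended without lithium male 1 (median -0.068) and stood at -0.13 without fluoxetine female 1 and -0.12 without lithium male 3. The others were kept without any single library, with ribosomal medians of 0.13 and 0.046 without fluoxetine females 1 or 2. Interferon response genes were lower in 14 of 16 cases by a median of -0.14 (adjusted p = 0.00389, and 0.894 with an estimated correlation). This call ended without fluoxetine female 1, fluoxetine male 1 or lithium female 3 (medians -0.071 to -0.057). Their scores were higher at higher olfactory bulb scores, which differed by -0.74 between lithium and fluoxetine (exact permutation p = 0.63). Myelin genes were higher in 17 of 17 cases by a median of 0.17 (adjusted p = 0.00484, and 0.894 with an estimated correlation). This call ended without fluoxetine female 3, lithium female 1 or lithium male 1 (medians 0.090 to 0.13) and was kept at 0.28 without lithium female 2. A batch term ended the glucocorticoid (-0.018) and interferon (-0.16) calls and took ribosomal, clock and myelin medians to 0.13, -0.15 and 0.49. Without the 6 bulb-high libraries the glucocorticoid (-0.12), interferon (-0.011) and myelin (0.076) calls ended, and ribosomal and clock genes stood at 0.13 and -0.13. Without the 4 Drd2/Ttr-high libraries ribosomal genes stood at 0.046.

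HT fluoxetine libraries were also set against WT vehicle libraries. Nuclear-encoded oxidative phosphorylation genes were lower in 41 of 43 cases by a median of -0.097, with 4 lower adjusted over the list alone. Clock genes were higher in 13 of 16 cases by a median of 0.18, with 8 higher and 1 lower adjusted over the list alone. All 15 glucocorticoid-induced genes were higher, by a median of 0.15, with 5 higher adjusted over the list alone, and astrocyte markers were higher in 12 of 14 cases by a median of 0.14, again with 5. In these lists limma called 0 members over all genes, while DESeq2 called Per1, Per2, Sult1a1 and Plin4. Camera called all 4 (adjusted p = 5.68e-13, 7.22e-08, 7.87e-08 and 1.06e-05), each call was kept without any single library, and fry gave adjusted p-values of 0.0421, 0.0324, 0.0324 and 0.0324. With an estimated correlation the adjusted p was 0.0782, 0.0516, 0.0510 and 0.0510, and the exact permutation p of scores was 0.005, 0.03, 0.01 and 0.05 (lowest adjusted p = 0.155). Without the 4 Drd2/Ttr-high libraries the oxidative phosphorylation median was -0.063. Glucocorticoid genes stood at 0.24 without WT female 1 and astrocyte markers at 0.094 without fluoxetine female 1.

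In the same comparison choroid plexus genes (12 of 12 higher, median 0.41, adjusted p = 3.5e-04) and microglial markers (11 of 14 higher, median 0.070, adjusted p = 0.00226, with 1 member higher adjusted over the list alone) were also called without any single library, and stood at 0.486 each with an estimated correlation. The choroid median was 0.17 without fluoxetine female 1, and the microglial one 0.11 without fluoxetine male 1 and 0.041 without WT female 1. Interferon genes (14 of 16 higher, median 0.14, adjusted p = 0.00336), myelin genes (16 of 17 lower, median -0.15, 0.00979) and endoplasmic reticulum stress genes (17 of 21 higher, median 0.051, 0.01) lost their calls with an estimated correlation (adjusted p = 0.696, 0.810 and 0.486). Presynaptic genes (17 of 20 lower, median -0.077, 0.0315), late activity genes (13 of 15 lower, median -0.082, 0.0398) and cholesterol genes (16 of 20 lower, median -0.047, 0.0493) lost them too (0.810, 0.639 and 0.810 with an estimated correlation). Leaving out fluoxetine male 1 ended 5 of these 6 calls, all but endoplasmic reticulum stress, with presynaptic and cholesterol medians of 0.025 and 0.019. The interferon call also ended without fluoxetine female 1 or WT male 2 (medians 0.032 to 0.099). The myelin call ended without fluoxetine female 3, fluoxetine male 3, WT female 1 or WT male 2 (-0.12 to -0.049). The endoplasmic reticulum call ended without fluoxetine female 2, fluoxetine male 2 or WT female 2 (0.027 to 0.046). The presynaptic call ended without fluoxetine female 1, WT females 1 or 3 or WT males 1 or 2 (up to -0.079). The late activity call ended without fluoxetine female 1, fluoxetine male 3, WT females 1 or 2 or WT males 1 or 3 (-0.091 to -0.018). The cholesterol call ended without fluoxetine females 1 or 3, WT female 1 or WT males 1 or 2 (up to -0.045). Kept calls moved without fluoxetine female 2 (myelin -0.23, presynaptic -0.13, cholesterol -0.092), fluoxetine male 2 (presynaptic -0.15, late activity -0.12, cholesterol -0.096), WT female 2 (presynaptic -0.12, cholesterol -0.097), fluoxetine female 3 (late activity -0.13) and fluoxetine male 3 (cholesterol -0.076). Without the 6 bulb-high libraries the choroid plexus, interferon, myelin, late activity, presynaptic and cholesterol calls ended, with medians of 0.036, 0.007, -0.13, -0.002, 0.035 and -0.002. A batch term ended the myelin (-0.093) and cholesterol (-0.045) calls and took late activity genes to -0.13. The cholesterol call also ended with no filter on low values, in the fit of only the groups compared and without the 4 Drd2/Ttr-high libraries (-0.047 to -0.040). limma called 0 genes, with 737 at an unadjusted p under 0.05, edgeR 0 and DESeq2 18. limma called 1 without WT female 1, 3 without WT male 2 and 2 without WT male 3.

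HT lithium libraries had higher oxidative phosphorylation genes than WT vehicle libraries (39 of 43, median 0.066), higher ribosomal protein genes (43 of 46, median 0.084) and higher astrocyte markers (13 of 14, median 0.077). Camera gave adjusted p-values of 5.03e-09, 5.03e-09 and 4.92e-04, kept without any single library, against 0.303, 0.602 and 0.178 with an estimated correlation. The ribosomal median was 0.052 without lithium female 1 and the astrocyte one 0.051 without WT male 1. Choroid plexus genes (12 of 12 higher, median 0.29, adjusted p = 0.00193), immediate early genes (15 of 20 higher, median 0.16, 0.00217), inhibitory neuron markers (12 of 15 lower, median -0.24, 0.0123) and autism risk genes (29 of 40 lower, median -0.029, 0.0192) were called as well, and stood at 0.602, 0.639, 0.178 and 0.372 with an estimated correlation. Inhibitory neuron scores were higher at higher olfactory bulb scores, which differed by -0.80 between these arms (exact permutation p = 0.52). The choroid plexus call ended without lithium male 1 or WT male 2 (medians 0.22 to 0.23) and was kept at 0.19 without lithium female 1 and 0.18 without WT male 1. The inhibitory neuron call ended without lithium male 3 (-0.089) and was kept at -0.39 without lithium male 1. The immediate early call ended without lithium female 3, lithium male 1, WT female 3 or WT male 1 (0.044 to 0.11), and with a batch term the list turned to -0.39 and was called lower; it was kept at 0.27 without the 6 bulb-high libraries and at 0.25 without WT female 2 or WT male 3. A batch term also ended the oxidative phosphorylation call (0.009) and took astrocyte, choroid plexus and autism risk medians to 0.14, 0.74 and -0.065. With the bulb score as a covariate inhibitory neuron markers stood at -0.083. The autism risk call ended without lithium female 1, lithium male 3, WT female 2 or WT males 1 or 2 (-0.037 to -0.024) and was kept at -0.046 without lithium male 1. Camera called 7 lists here and 11 without lithium female 2. limma called 0 genes, with 431 at an unadjusted p under 0.05, edgeR 0 and DESeq2 5, and limma called 1 without WT male 1.

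With both sexes together, the lists that follow were not called by camera in any comparison between arms. In the order HT against WT, fluoxetine against vehicle and lithium against vehicle, excitatory neuron markers had medians of -0.064, -0.038 and 0.067 (adjusted p = 0.5, 0.716 and 0.576). Oligodendrocyte precursor genes had 0.034, -0.018 and -0.002 (0.382, 0.975 and 0.840). Endothelial and pericyte genes had -0.004, -0.019 and 0.019 (0.859, 0.665 and 0.549). GABA-A receptor genes had -0.02, -0.036 and -0.011 (0.145, 0.975 and 0.813). Mitochondrially encoded genes had -0.008, 0.044 and 0.004 (0.884, 0.975 and 0.855), with a mean of opposite sign for fluoxetine, -0.057. Wnt targets had 0.003, 0.028 and -0.008 (0.884, 0.410 and 0.951), and inositol metabolism genes -0.044, 0.016 and -0.01 (0.142, 0.590 and 0.941). Serotonin receptor and turnover genes had -0.038, -0.077 and -0.053 (0.594, 0.858 and 0.599). Calcineurin genes had 0.008, -0.033 and -0.027 (0.831, 0.665 and 0.678), extracellular matrix genes -0.011, 0.049 and -0.015 (0.884, 0.354 and 0.900), and chromatin regulators -0.023, 0.025 and 0.012 (0.370, 0.354 and 0.847). Red blood cell genes had -0.12, 0.23 and 0.21 (0.142, 0.0902 and 0.0531). The mean also had the opposite sign to the median for Wnt targets with genotype (-0.01), oligodendrocyte precursor genes with fluoxetine and lithium (0.038 and 0.03), and GABA-A receptor, mitochondrially encoded and inositol genes with lithium (0.006, -0.014 and 0.027). Immediate early genes had a median of -0.046 and a mean of 0.02 with genotype (adjusted p = 0.963), and choroid plexus genes a median of 0.089 and a mean of -0.063 with lithium, neither called.

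Within each sex no gene passed the genotype test. limma called 0 in females, with 538 at an unadjusted p under 0.05, and 0 in males, with 308. edgeR called 0 in each, and DESeq2 called 2 in females, among them Hif3a, and 0 in males. Without WT female 3, limma called 1 in females. Fluoxetine gave 0 in females (500 unadjusted) and 0 in males (556), against 0 and 0 by edgeR and 2 and 2 by DESeq2. Without fluoxetine female 1, limma called 1 in females. Lithium gave 0 in females (266 unadjusted, 0 by edgeR, 2 by DESeq2). In males it gave 1 of 451 unadjusted, Xist, the RNA that silences an X chromosome (2.74 ± 0.42, adjusted p = 0.0481), against 0 by edgeR and 9 by DESeq2. The 3 lithium males had 12 to 17 reads of Xist, other males 0 to 8 and females 17786 to 45821. Each of the 6 omissions ended that call (2.63 to 2.92, adjusted p = 0.124 to 0.489), as did rescaling by trimmed means, a pseudocount of 8 (1.29), a batch term, the fit of only the groups compared and leaving out the 4 Drd2/Ttr-high libraries. Tests of whether an effect differed between the sexes called 0 genes for genotype, fluoxetine and lithium (365, 180 and 274 unadjusted), with 0 each by edgeR and 1, 0 and 0 by DESeq2.

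Gene lists within a sex gave several camera calls, none of which held with an estimated correlation. In HT females all 14 microglial markers were higher by a median of 0.20 (camera adjusted p = 4.76e-12, and 0.0977 with an estimated correlation), against 0.002 in males. Immediate early genes were lower in HT females in 18 of 20 cases by a median of -0.42 (1.54e-08, and 0.196 with an estimated correlation) and higher in HT males in 19 of 20 by 0.40 (1.18e-09, and 0.820 with an estimated correlation). The test of the difference between the sexes gave 4.99e-07 for microglia and 5.75e-17 for immediate early genes (0.301 and 0.158 with an estimated correlation). Immediate early scores were higher where the olfactory bulb score was higher, and the bulb score differed by -2.13 between HT and WT females and by 0.32 between HT and WT males. With fluoxetine, oxidative phosphorylation genes were lower in 40 of 43 cases in females (median -0.11, 1.26e-13) and in 39 of 43 in males (-0.11, 5.69e-10), with 0.269 and 0.216 with an estimated correlation. All 15 glucocorticoid-induced genes were higher in fluoxetine males by a median of 0.29 (9.67e-09, and 0.0610 with an estimated correlation), against -0.007 in females (mean 0.056). With lithium all 43 oxidative phosphorylation genes were higher in females by a median of 0.11 (2.98e-15, and 0.187 with an estimated correlation), against -0.036 in males. Camera called 7 and 3 lists for genotype in females and males, 6 and 9 for fluoxetine, and 9 and 4 for lithium.

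Males against females over all 24 libraries differed in genes of the sex chromosomes, the haemoglobin gene Hba-a2 and Trmt1l (chromosome 1, -0.12 ± 0.02, adjusted p = 0.0499), named after its values were seen. limma called 14 genes, 7 higher and 7 lower in males, of 435 at an unadjusted p under 0.05, and edgeR called 13 and DESeq2 20, Trmt1l included. The Y-linked genes Ddx3y (10.18 ± 0.09, adjusted p = 1.01e-23), Uty (8.53 ± 0.11), Kdm5d (9.58 ± 0.17) and Eif2s3y (9.68 ± 0.19) and the X-linked Xist (-12.71 ± 0.21) had the smallest p, and with a pseudocount of 8 Uty stood at 5.63. Ddx3y had 1180 to 2105 reads in males and 0 or 1 in females. All 5 red blood cell genes rose in males, by a median of 0.67 (camera adjusted p = 1.63e-20, and 0.00808 with an estimated correlation). In limma all 5 passed adjusted over the list alone and 1 over all genes (4 in DESeq2), Hba-a2, which can share reads with its near-identical copy (0.68 ± 0.11, adjusted p = 0.00777). Camera also called glucocorticoid-induced genes (median -0.14, adjusted p = 2.09e-06), oxidative phosphorylation (0.024, 0.0013), endoplasmic reticulum stress (-0.027, 0.00155, 2 lower adjusted over the list alone) and microglial genes (0.046, 0.00366). With an estimated correlation these stood at adjusted p = 0.0963, 0.847, 0.397 and 0.847.

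Drug and genotype effects were negatively correlated across genes, by about as much as in simulations of unchanged groups with the same shared controls. Across 16825 genes, which are not independent replicates, the log2 fold changes of fluoxetine and genotype had r = -0.537, and those of lithium and genotype r = -0.51. Both use the same HT vehicle libraries, and 1000 simulations without any effect gave -0.477 and -0.476 on average. The covariances were -0.0200 and -0.0198, against simulated values of -0.0269 and -0.0279, differences of 0.00682 and 0.00808. With the HT vehicle libraries divided into sets of 3 so that none was shared, r was 0.082 and 0.079 over 18 splits. The drugs shared 0 called genes, where independent lists would share 0 higher and 1.19e-04 lower, and 1 of 50 simulations of unchanged groups gave any. With split controls the highest number shared over 9 pairs was 0.

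Libraries within each arm differed in transcripts of the olfactory bulb, which lies in front of the prefrontal cortex. The mitral cell gene Cdhr1 ran from 36.9 to 8456 normalised counts, Doc2g from 54.4 to 6972 and the dopamine synthesis gene Th from 20.9 to 2339. A score of 9 such genes, chosen after principal components were seen, ran from -3.46 to 3.12. It followed the first component (r = 0.958), which held 38.9% of the variance, so its relations to lists are not independent of that choice. Across the 24 libraries the bulb score was related to the scores of inhibitory neurons (Pearson r = 0.972, Spearman rho = 0.968, permutation p = 1e-05 for each, the smallest they can give), with r = 0.966 without the 2 farthest libraries and 0.982 and 0.978 within batches. Glutamate receptor genes had r = -0.646 and rho = -0.643 (permutation p = 0.00071 and 0.00098), with -0.557, -0.626 and -0.702. Cholesterol genes had r = -0.67 and rho = -0.569 (permutation p = 0.00036 and 0.00445), with -0.649, -0.68 and -0.649. For interferon genes r was 0.696 and rho 0.69 (permutation p = 9e-05 and 0.00027), with r = 0.71 without the 2 farthest, and 0.856 and 0.123 within batches, so the relation did not hold in the batch of 7. The adjusted p of r for these 4 lists was 4.43e-05, 0.00183, 0.00101 and 2.79e-04. Clock genes had r = -0.593 and rho = -0.643 (permutation p = 0.00234 and 0.00104), with -0.587 without the 2 farthest and -0.594 and -0.59 within batches. Immediate early genes had 0.553 and 0.53 (permutation p = 0.00506 and 0.00902), with 0.53, 0.581 and 0.598. Astrocyte markers had 0.548 and 0.508 (permutation p = 0.00599 and 0.0127), with 0.615, 0.685 and, in the batch of 7, -0.058. Ribosomal genes had 0.508 and 0.565 (permutation p = 0.0112 and 0.00468), with 0.472, 0.591 and 0.316. Choroid plexus genes had 0.478 and 0.493 (permutation p = 0.0186 and 0.0162), with 0.442, 0.494 and 0.624. The adjusted p of r for these 5 was 0.00558, 0.0112, 0.0124, 0.0217 and 0.032. In all, 18 of 31 relations passed adjustment by r. Among those that did not were microglia (r = -0.409, rho = -0.39, permutation p = 0.0487 and 0.061, -0.379 without the 2 farthest, -0.278 and -0.96 within batches) and oxidative phosphorylation (r = -0.284, rho = -0.357, permutation p = 0.18 and 0.0889), with adjusted p of r of 0.0686 and 0.232.

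**Figure D4:**
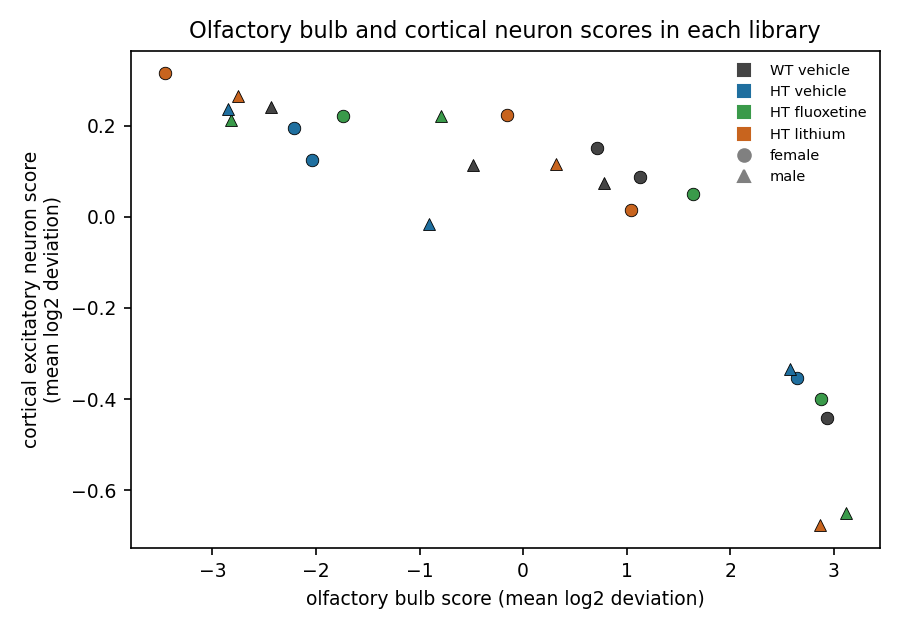
Olfactory bulb score (x axis) against excitatory neuron score (y axis), both as mean log2 deviation, for each of 24 libraries, coloured by arm with circles for females and triangles for males. Bulb scores run from -3.46 to 3.12, and every arm has libraries near both ends.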

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

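Of the tests in this part, the camera tests of a difference between the sexes, the bulb score against gene length, GC content and group, and those on genes without reads in one batch, were chosen only after the result was seen, as was the bulb score covariate in the oxidative phosphorylation test.

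Some libraries lay far from the other 5 of their arm, and chance alone does this in about 1 in 20 groups; it occurred for 10 of 128 list scores and 32 of 340 gene levels. HT vehicle male 1 was high for striatal genes, with a list score of 2.47, Pde10a at 7853, Scn4b at 10130, Drd2 at 1379, Gpr6 at 374.9 and Syndig1l at 1355, and also for Epb41 at 1813 and Rpl38 at 2744. Lithium female 1 was high for the same list at 0.33, with Drd2 at 81.26 and Gpr6 at 95.77, and WT female 1 for Drd2 at 370.8 and Gpr6 at 243.6. Ttr was high in HT vehicle female 1 (3407), fluoxetine female 2 (780.9), WT male 3 (74.28) and lithium female 3 (44.95). HT vehicle female 1 also stood apart for Kl (187.7), Hspa1a (492.7) and, on the low side, Axin2 (832.9). lithium male 1 had low scores for excitatory neurons (-0.68), presynaptic genes (-0.4) and cholesterol genes (-0.22), a high calcineurin score (0.08), low Fgfr3 (2533), Scn4b (844.1) and Cx3cr1 (1118), and high Epb41 (1453). WT female 2 was low for excitatory neurons (-0.44), presynaptic genes (-0.27) and Fam221b (29.27). The oxidative phosphorylation score was low in fluoxetine female 2 (-0.19) and the interferon score in lithium female 3 (-0.38). Single genes apart were Eva1a in HT vehicle male 2 (211.4, low), Hif3a in WT male 2 (361.1), Ctss and Rpl15-ps3 in WT male 3 (1623 and 118.2), Sox9 in fluoxetine male 2 (694.4), Hspa5 in fluoxetine male 3 (4992, low), Gm12671 in fluoxetine male 1 (316) and Nr4a3 in fluoxetine female 3 (1343). Pdia4 was high (863.7) in lithium male 1.

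Camera also called differences between the sexes in the effect on 18 lists, given here as males minus females. For genotype they were microglia (-0.217), striatal genes (0.704), immediate early genes (0.827), late activity genes (0.174), ribosomal proteins (0.097), endoplasmic reticulum stress (0.087) and chromatin regulators (0.078). For fluoxetine they were astrocytes (0.099), microglia (0.154), glucocorticoid-induced genes (0.251), heat shock (0.092) and autism risk genes (-0.101). For lithium they were striatal genes (-0.737), immediate early genes (0.314), oxidative phosphorylation (-0.138), ribosomal proteins (-0.079), glucocorticoid-induced genes (0.227) and endoplasmic reticulum stress (-0.086). None held, the lowest adjusted p being 0.131 with an estimated correlation.

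Olfactory bulb transcripts differed strongly between libraries of one group. Excitatory neuron scores lie apart in 6 libraries, those with the highest bulb scores, so the rank relation of both scores over all 24 (rho = -0.89) rests in part on that gap; within the other 18 libraries r was -0.742 and rho -0.751 (permutation p = 0.00066 and 0.00047), and within the 6 r was -0.742 and rho -0.657 (exact permutation p = 0.104 and 0.175). The slope of genes on the score was unrelated to exon length (r = 0.004 across genes) or GC content (0.003), and the 8 groups held 13.9% of its variance, where 30.4% arises by chance, which argues against these as the source. Tissue of the olfactory bulb in some dissections may account for it, as the values it needs are there; none of the 9 genes is in another list, and 7 were above 0 in every library, so cortex itself may hold some.

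Genes without any read in batch P40_L2 and with a median of at least 5 reads in the other batch numbered 6 (Rpl15-ps3, Rps6-ps4, Gm12671, Pet117, Gm28048 and Gm47924), where 100 random sets of 7 libraries gave at most 3. Chosen without the fluoxetine libraries, as genes at 0 in all 6 lithium libraries with a median of at least 5 reads in the 12 vehicle libraries, 5 of them were found; 5 of 5 were at 0 in the fluoxetine library of that batch against 0 to 3 in each of the 5 fluoxetine libraries of the other, so a difference between batches may account for them. Lithium cannot be told apart from batch with only 1 fluoxetine library there. Of the 6, 4 are processed pseudogenes, against 2.1% of the table (Fisher's exact p = 2.75e-06), so the sharing of reads with near-identical copies may take part.

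Oxidative phosphorylation genes lower with fluoxetine kept a median of -0.105 with the bulb score as a covariate, of -0.124 without the fluoxetine library of the other batch, and only 0.24% of 10000 random lists matched on expression and exon length had a median as low. These values argue against bulb tissue, batch and short transcripts as the whole cause. The random lists had a median of -0.055 (-0.118 to 0.003), so part of the shift is common to genes of such length and level. With an estimated correlation the list was called neither before nor after (adjusted p = 0.146, 0.121 and 0.138), so chance stays open, and an effect of the drug, which the design names, is a hypothesis.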

How the results depend on the processing

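Estimated correlation and leaving out libraries were planned, as were the batch term, filters, pseudocount, rescaling, block and restricted fits; the count tests, the bulb score covariate, the omission of 6 or 4 libraries, the permutation test of list scores and the camera test of sex differences were tests chosen after the data were seen. The cause of a changed result was not tested, except that fewer libraries or genes enter some fits. Over all settings 267 gene counts and 120 list counts stayed within 1.5 times, while 93 and 18 moved by more. Of values, 2514 for named genes kept their side of the threshold, and 906 for lists side and direction. A call was lost by 139 gene and 207 list values and gained by 13 gene values. Also, 48 uncalled gene values moved by more than their standard error and 14 list tests turned. The Dyrk1a difference of 0.099 kept its sign in all 15 alternatives, with p under 0.05 by the exact permutation test, or by limma for the batch term. The batch term could not move this value, as all vehicle libraries are in batch P40_L1. Depth limits low genes, and no alternative was left unrun.

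Counts of called genes that moved were these. Rescaling gave 0 for lithium in males. A mean of at least 50 gave 1 for lithium and 1 for HT fluoxetine against WT. A pseudocount of 8 gave 0 for lithium and 0 in lithium males. The batch term gave 1 for fluoxetine, 1 for lithium, 1 for HT lithium against WT, 1 for lithium against fluoxetine, 1 for lithium females and 0 for lithium males. Fits of only the groups compared gave 0 for fluoxetine, 4 for lithium, 0 for lithium against fluoxetine, 4 for lithium females, 2 for lithium males and 1 for the lithium sex difference. edgeR gave 0 for lithium and 0 for lithium males. DESeq2 gave 16 for fluoxetine, 18 for HT fluoxetine against WT, 5 for HT lithium against WT, 30 for lithium against fluoxetine, 2 for genotype in females, 2 and 2 for fluoxetine in females and males, 2 and 9 for lithium in females and males, and 1 for the genotype sex difference. The bulb score covariate gave 5 for genotype, 4 for fluoxetine, 7 for HT fluoxetine against WT, 4 for HT lithium against WT, 13 for lithium against fluoxetine and 2 for lithium males. Without the 6 libraries highest in bulb transcripts counts were 0 for fluoxetine, 1 for lithium and 2 for lithium against fluoxetine. Without the 4 highest in Drd2 or Ttr they were 0 for fluoxetine, 0 for lithium, 0 for lithium against fluoxetine, 1 for lithium females and 0 for lithium males.

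Leaving out 1 library gave ranges of 0 to 1 for genotype, 0 to 2 for fluoxetine, 0 to 0 for lithium, 0 to 3 for HT fluoxetine against WT, 0 to 1 for HT lithium against WT, 0 to 6 for lithium against fluoxetine, 0 to 1 for genotype females, 0 to 1 for fluoxetine females and 0 to 0 for lithium males. Lists called ranged from 4 to 16 for genotype, 5 to 12 for fluoxetine, 3 to 11 for lithium and 5 to 11 for HT lithium against WT.

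With an estimated correlation camera called 0 lists for genotype, fluoxetine, lithium, HT fluoxetine against WT and HT lithium against WT, and 1 for lithium against fluoxetine. The bulb score covariate gave 14 lists for genotype and 13 for HT lithium against WT, the batch term 4 for lithium and 11 for HT lithium against WT, and leaving out the 6 libraries 3 for lithium against fluoxetine.

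Lists whose median or test turned were, with a batch term, microglia (0.106), immediate early (-0.317), late activity (-0.069) and oxidative phosphorylation (0.009, by the test) for lithium, and immediate early genes (-0.387) for HT lithium against WT. Leaving out 1 library gave -0.688 to 0.116 for striatal genes with fluoxetine, -0.812 to -0.07 with lithium, -0.006 to 0.274 for myelin with lithium, and -0.149 to 0.025 for presynaptic and -0.097 to 0.019 for cholesterol genes in HT fluoxetine against WT. Without the 4 libraries striatal genes stood at -0.075 with fluoxetine and 0.001 with lithium. Without the 6, myelin stood at 0.009 with lithium, presynaptic genes at 0.035 in HT fluoxetine against WT and choroid plexus genes at -0.06 with genotype. Halving the HT vehicle libraries gave r = 0.082 for fluoxetine and 0.079 for lithium against genotype.

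The replicate numbers do not pair the libraries: 36 same-numbered pairs had residual correlations of -0.7 to 0.72 (median -0.06, 12 over 0.1), and 7 of 24 libraries correlated best with their own number. The replicate block, of 6 blocks, gave 0 called genes for fluoxetine, lithium, lithium against fluoxetine and lithium males.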

Other observations

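Tests with the bulb score as a covariate were chosen only after the result was seen, and the library splits were set beforehand.

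With the bulb score as a covariate the median standard error fell from 0.10 to 0.078, and limma called 5 genes for genotype. They were the zinc finger gene Hivep1 (-0.27, adjusted p = 0.0271), the Ras pathway inhibitor Spred2 (-0.26, 0.0271), Mxd4 (0.26, 0.0283), Homer1 (-0.45, 0.0497) and Eva1a (0.39, 0.0497). For fluoxetine the 4 called genes were P4ha1 (0.32, 0.0108), Spred2 (0.28, 0.0108), Ndufs3 (-0.23, 0.0114) and Per2 (0.45, 0.0265). In HT fluoxetine against WT libraries 7 genes were called higher, among them the lipid transporter Mfsd2a (0.44, 0.0178), the mitochondrial carrier Ucp2 (0.46, 0.0178), the BMP target Id1 (0.51, 0.0178), the syndecan Sdc4 (0.42, 0.0272) and the Wnt receptor Fzd2 (0.42, 0.0353). Without the covariate limma called none of these 5 (adjusted p = 0.0558, 0.523, 0.568, 0.115 and 0.310), while DESeq2 called Mfsd2a, Sdc4 and Fzd2 (8.15e-06, 1.74e-04 and 0.0198).

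Random splits of the same libraries were drawn for each count, 100 for the comparisons of arms and 10 within a sex. Where 0 genes were called, with genotype, HT fluoxetine against WT and HT lithium against WT, all 100 splits necessarily gave as many (highest others 2, 1 and 1), so the splits say nothing about chance there. This also holds for the differences between sexes for genotype, fluoxetine and lithium, with 100 of 100 splits and highest others of 2, 3081 and 1. The counts that follow include the real arrangement. For fluoxetine 3 of 100 splits gave as many as the 2 genes called. For lithium the real arrangement, with 2, was the 1 that reached its count (highest other 1). For lithium against fluoxetine 2 gave as many as 4 (highest other 32), and for males against females 2 gave as many as 14 (highest other 2041). Few splits reach these 4 counts, but shares are unadjusted. Lithium libraries are all in P40_L2, so batch stays open there. The highest other fluoxetine split called 3081 genes, with a bulb score difference of 4.1 (0.84 in the real one). It and the one with 2041 point to sample structure.

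Within a sex 10 splits are too few for a share under 0.05. The real counts were 0 with highest others of 0 and 1 for genotype in females and males, 0 with 1 and 0 for fluoxetine, and 0 and 1 with 0 and 0 for lithium, where 10, 10, 10, 10, 10 and 1 splits gave as many, the real one included; a count of 0 is matched by every split.

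Numbers of lists called by camera were no larger than splits give. The 9, 7, 8, 12, 7 and 6 lists for genotype, fluoxetine, lithium, HT fluoxetine against WT, HT lithium against WT and lithium against fluoxetine were matched by 43, 78, 45, 25, 63 and 80 of 100 splits, with highest others of 15, 16, 15, 16, 17 and 15, so chance cannot be excluded for these counts.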
